A study of Mus musculus with 25 samples.

How the data were processed

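Expression in brain cortex was measured by RNA sequencing in 25 mice: 5 each of wild-type mice given vehicle, wild-type mice given high P, 5xFAD mice given vehicle, 5xFAD mice given low P and 5xFAD mice given high P. The mice of a group are separate animals per the series design; their age, the doses and the duration of treatment are not given in the sources used here, nor is any litter, batch or pairing. Groups and replicate numbers were taken from the labels.

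Libraries were strand-specific and made from poly(A)-selected RNA with random priming, selection of fragments by size and PCR, per the labels' protocols. Reads were aligned to mm10 with HISAT2, whose version is not given in the sources used here, per the submitters' processing notes; the counting tool and annotation are not given there. The deposited table holds FPKM values computed by the authors for 54532 genes in each of the 25 libraries, with Ensembl identifiers, symbols, coordinates and gene lengths. A gene length is a length in bp that the authors deposited in a separate column of that table. The identifiers of 54409 genes were found in a GENCODE mouse annotation, 98.3% of them with the same coordinates, and a symbol shared by several genes, of which there were 103, was kept apart by its identifier. GC content was taken from that annotation's transcripts and known for 99.9% of the tested genes.

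Multiplying each FPKM by gene length gave whole multiples of a fixed step in each library for 100% of the nonzero values (tolerance 0.01 of a read, largest distance 1.27e-05), so reads assigned to genes could be recovered. They ranged from 15518358 to 17698222 per library with a mean of 16712409. At this depth the median SE of a log2 fold change was 0.15 for comparisons of 5 with 5 mice and 0.213 for the interaction. The library sizes behind the deposited FPKM were proportional to median-of-ratios factors over genes, so that scaling by such factors moved nothing and tested nothing. No pair of libraries matched within counting noise (smallest chi-square per gene 5.31), and all were used. PCR duplicates cannot be recognised in such values, so read numbers near 0 cover counting error only.

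The following choices were fixed before the data were examined. Genes with at least 0.5 FPKM in at least 5 libraries were tested (16450). Values were transformed as log2(FPKM + 0.5), with 0.5 as the pseudocount, and a fold change on that scale understates the change of low genes. A linear model with a mean per group was fitted to all 25 libraries with limma 3.58.1 in R 4.3.3 (tables read with data.table, version 1.17.8), with moderated variances that follow intensity and 20 residual degrees of freedom. The 6 contrasts were AD_Veh against WT_Veh, WT_HighP against WT_Veh, AD_LowP and AD_HighP each against AD_Veh, AD_HighP against AD_LowP, and the interaction of genotype with high P. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method within a contrast, and a gene was called at an adjusted p under 0.05. Where the text says "adjusted over the list alone", the adjustment was made over the tested members of that list.

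Gene lists were written by hand for the cell types, immune and stress pathways and neighbouring tissues that a cortical sample of an amyloid model could hold. Of 33 lists with 725 symbols (11 of them in more than 1 list), 32 had at least 5 tested members. They were plaque-associated microglia, homeostatic microglia, complement, antigen presentation, interferon response, inflammatory cytokines and sensors, reactive astrocyte, astrocyte, oligodendrocyte and myelin, oligodendrocyte precursor, excitatory neuron, inhibitory neuron, synapse, immediate early genes, endothelial and mural, meninges and fibroblast, choroid plexus, striatum, hippocampus, thalamus and hypothalamus, red blood cell, mitochondrially encoded, nuclear oxidative phosphorylation, cytosolic ribosomal protein, unfolded protein response, heat shock response, antioxidant response, cholesterol synthesis, autophagy and lysosome, amyloid precursor protein processing and clearance, circadian clock and glucocorticoid response. The remaining list, of blood leukocytes, had 4 of 20 members expressed and was not tested. Each list was compared with the other genes by camera in limma with a preset correlation of 0.01, and again with the correlation estimated per list; fry tested whether the members moved on balance in 1 direction or, in its mixed form, in either. A score per mouse, the mean of standardised log2 values over the members, was compared by exact permutation of 5 against 5 mice, where the smallest two-sided p is 0.00794. List p-values were adjusted over the 32 lists of a contrast.

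Genes were named by a rule. App and Thy1 were named as a check of the genotype labels. Of the called genes with a mean of at least 1 FPKM and no overlap between the 2 groups, leaving out unnamed gene models, pseudogenes and receptor segments, the 10 with the largest rise and the 10 with the largest fall were named. For each list described, up to 4 members with the smallest p were named. Some genes that the rule names are not reported here. If fewer than 5 genes were called, all were named, and if none, the 5 with the smallest p. Ttr, Mir124a-3 in groups other than AD_HighP and AD_Veh, and the genes left after the GC correction were named after their values were seen.

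The steps were tested on simulated libraries drawn from the real depths and from each gene's mean and within-group spread pooled over all groups. For each contrast, 100 genes were changed by each fold among the 16450, drawn at random from genes above a minimum mean read number. Of genes changed by 1.5-fold, 41% were called for genotype, 49% for high P in WT mice, 26% for low P, 40% for high P in AD mice, 44% for high against low P and 16% for the interaction; of genes changed by 2-fold, 80%, 80%, 70%, 71%, 75% and 49%. Between 1 and 11 unchanged genes were called per contrast. The pairwise contrasts shared these means and this spread. Their shares of called genes therefore differ mainly by the genes drawn and do not rank the comparisons. In these simulations both libraries and genes varied independently, with no GC-dependent differences. A simulated list of 30 genes shifted by 1.25-fold gave a camera p between 3.83e-24 and 1.13e-13, and an unchanged list between 0.288 and 0.97. The members of these lists were uncorrelated, while the correlation estimated within the real lists reached 0.92 (striatum). The simulated lists therefore could not test whether the preset correlation holds for the real ones. For the return of genotype genes, a simulated slope of -0.5 was recovered as -0.428 over 10 simulations.

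The alternatives planned were pseudocounts of 0.1 and 1, no filter or a filter of 1 FPKM on the mean, median-of-ratios and quantile scaling, a replicate block, a sex marker covariate, a fit to only the groups compared, no intensity trend, array weights, a fold minimum of 1.5, a count test on recovered reads (limma voom), other list tests and leaving out each library in turn. Chosen after seeing the data were a correction of each library for GC content (loess, span 0.5), the GC slope or the striatum score as covariates, the GC correction with the replicate block, scaling to total assigned reads without mitochondrial genes, fits without 4 libraries with high Ttr, and fits of 1 sex. For a contrast, only results without a library of its own groups were counted as left-out settings. Permutation tests of a single value, simulations and splits used fixed seeds. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15 (pandas 2.3.3, numpy 2.4.6).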

Results

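Cortical RNA was sequenced from 25 mice in 5 groups of 5: wild-type mice given vehicle (WT_Veh) or a high dose of P (WT_HighP), and 5xFAD mice given vehicle (AD_Veh), a low dose (AD_LowP) or a high dose (AD_HighP). The 5xFAD line is a transgenic model of amyloid deposition whose transgenes, including mutant human APP, are driven by Thy1 sequences, and P is a natural product derivative whose identity and doses are not given in the sources used here. Each library held between 15518358 and 17698222 reads assigned to genes. The group means were 16831424 ± 343298 reads in WT_Veh, 16934040 ± 499962 in WT_HighP, 16270246 ± 196747 in AD_Veh, 17117009 ± 478606 in AD_LowP and 16409324 ± 557234 in AD_HighP (SD, n = 5 each). AD_Veh libraries were shallower than those of WT_Veh (two-sided exact permutation p = 0.0238) and of AD_LowP (exact p = 0.00794). Of the 54532 genes listed, 21780 were at 0 in every library and 16450 were tested. By Xist and Y-linked genes, each group held 3 males and 2 females. All levels below are group means of FPKM ± SD over 5 mice, and fold changes are on the log2(FPKM + 0.5) scale with their standard error (SE).

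The comparison of vehicle-treated genotypes asked how the cortical transcriptome of 5xFAD mice differed from that of wild-type mice. The transcript of Cst7, a cystatin that inhibits lysosomal cysteine proteases in microglia, rose from 0.401 ± 0.308 FPKM in WT_Veh to 56.8 ± 16.6 in AD_Veh (log2 fold change 6.01, SE 0.26, adjusted p = 1.2e-13). Gfap, the intermediate filament of reactive astrocytes, rose from 27.1 ± 7.26 to 354 ± 90 FPKM (log2 3.69, SE 0.21, adjusted p = 2.61e-11). Cd74, the invariant chain of MHC class II, rose from 1.5 ± 0.939 to 27.8 ± 4.93 FPKM (log2 3.97, SE 0.38, adjusted p = 1.34e-07). Thy1, whose regulatory sequences drive the transgenes, rose from 155 ± 15.6 to 458 ± 78 FPKM (log2 1.55, SE 0.13, adjusted p = 1.8e-08). The mouse gene App (139 ± 10.5 against 145 ± 5.8 FPKM, adjusted p = 0.807) was not called. In all, 465 genes were higher and 45 lower in AD_Veh, and 403 of these 510 differed by at least 1.5-fold.

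In mm10, Thy1 (ENSMUSG00000032011) lies on chromosome 9 from 44043384 to 44048579, Cst7 (ENSMUSG00000068129) on chromosome 2 from 150570415 to 150578944. Gfap (ENSMUSG00000020932) lies on chromosome 11 from 102887336 to 102900912 and Cd74 (ENSMUSG00000024610) on chromosome 18 from 60803848 to 60812646, and all 4 are protein-coding. Among the other large rises, the integrin Itgax reached 7.95 ± 2.9 FPKM from 0.0648 ± 0.0364 (log2 3.83, SE 0.21). The secreted protease inhibitor Serpina3n reached 71.8 ± 28.7 from 5.67 ± 1.06 (log2 3.46, SE 0.26). The complement gene C4b reached 68.9 ± 17.5 FPKM from 5.99 ± 1.11 (log2 3.40, SE 0.22). Its reads can be shared with its close copy C4a, so its level is uncertain. The chemokines Ccl3 (9.53 ± 2.78 against 0.468 ± 0.121 FPKM) and Ccl6 (7.31 ± 0.877 against 0.686 ± 0.119) rose as well. The glycoprotein Gpnmb (7.69 ± 4.67 against 0.371 ± 0.18) and the MHC class II chain H2-Ab1 (4.71 ± 0.867 against 0.321 ± 0.309) also rose, and the log2 fold changes of these 4 lay between 2.72 and 3.33.

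**Figure D1:**
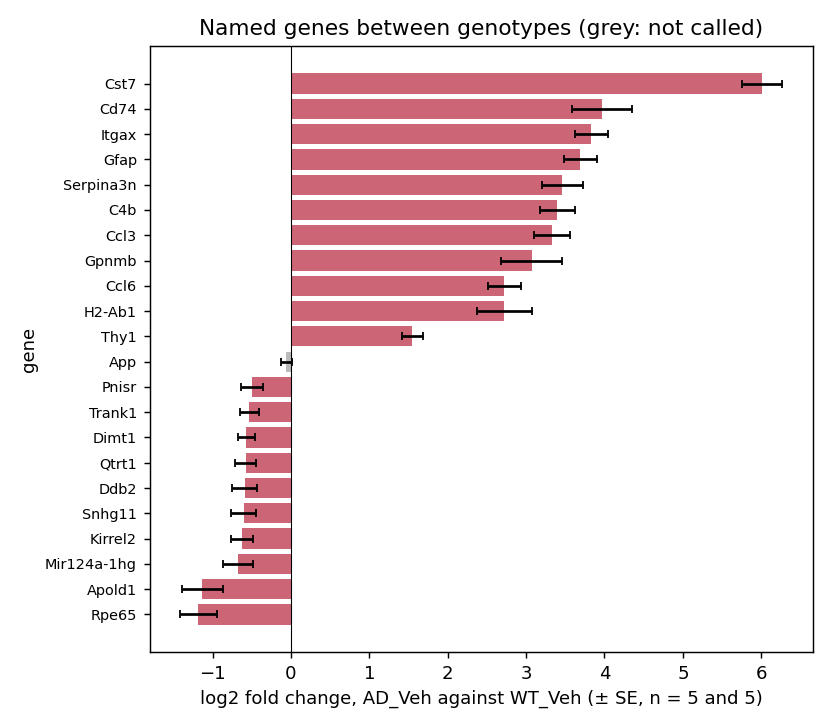
Bars give the log2 fold change of each named gene in AD_Veh against WT_Veh with its standard error (5 mice per group); grey bars mark genes that were not called. The largest rise is that of Cst7 at 6.01 and the largest fall that of Rpe65 at -1.18, while App lies at -0.06.

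Among the gene lists, that of plaque-associated microglia moved furthest, with 31 of 32 tested members higher (32 adjusted over the list alone), none lower, and a median log2 fold change of 1.81 (adjusted p = 2.2e-108). Its members included the pattern receptor Clec7a (log2 3.81) and the lysosomal protease Ctsd (269 ± 48.5 against 77.2 ± 6.61 FPKM, log2 1.78). Of 15 homeostatic microglia genes, 9 rose and 6 did not pass (13 higher adjusted over the list alone; median 0.86, adjusted p = 4.11e-25). Among them were Fcrls, the chemokine receptor Cx3cr1 (28.5 ± 2.54 against 12 ± 2.24) and the growth factor receptor Csf1r. Reactive astrocyte genes rose in 11 of 21 cases (16 adjusted over the list alone; median 0.81, adjusted p = 8.95e-30). General astrocyte markers gave a median of 0.01 (adjusted p = 0.32), with the water channel Aqp4 alone called (40.5 ± 11.6 against 20.8 ± 5.36 FPKM). Interferon response genes rose in 17 of 24 cases, including Oasl2 (log2 1.24) and Ifitm3 (log2 1.23), with 23 higher adjusted over the list alone (median 0.83, adjusted p = 8.24e-31). Antigen presentation genes rose in 10 of 22 cases (19 adjusted over the list alone; median 0.74, adjusted p = 5.02e-26). The class I members H2-K1 and H2-D1, with log2 fold changes of 1.21 and 1.51, are similar in sequence and can share reads. Complement genes rose in 9 of 16 cases (11 higher and 1 lower adjusted over the list alone; median 0.99, adjusted p = 7.35e-19). Besides C4b, they included the integrin chain Itgb2 (log2 1.76), the receptor C3ar1 (log2 1.37) and C1qa (97.4 ± 27.3 against 20.1 ± 6.65 FPKM). Among cytokines and innate sensors, 7 of 19 rose (11 higher and 2 lower adjusted over the list alone; median 0.59, adjusted p = 4.46e-12). Among them were Cd14 (10.1 ± 2.24 against 1.66 ± 0.644 FPKM) and Tlr2 (log2 1.61).

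Genes of lysosomes and of sterol synthesis also rose. In the autophagy and lysosome list, 12 of 36 members rose (13 adjusted over the list alone; median 0.14, adjusted p = 3.97e-15). Among them were the protease Ctss (119 ± 19.7 against 35.3 ± 4.45 FPKM) and the lysosomal membrane protein Laptm5 (36.4 ± 6.3 against 10.3 ± 1.76). In the cholesterol synthesis list, 8 of 26 rose (13 adjusted over the list alone; median 0.32, adjusted p = 1.82e-11). These included Acat2 (log2 0.48), Fdft1 (log2 0.35) and Sqle (log2 0.44). These 9 lists held with a correlation estimated per list (adjusted p from 1.23e-06 to 0.00967) and by per-mouse scores (exact p = 0.00794 and adjusted p = 0.0282 each). Another 6 lists passed with the preset correlation but not with an estimated one. Oligodendrocyte and myelin genes had a median of 0.43, with 2 of 19 higher adjusted over the list alone (adjusted p = 9.05e-06, but adjusted p = 0.431 with an estimated correlation). Cytosolic ribosomal proteins had a median of 0.17, with 3 of 47 higher adjusted over the list alone (adjusted p = 4.09e-09, but adjusted p = 0.295 with an estimated correlation), and passed mixed fry (adjusted p = 0.038). Antioxidant genes had a median of 0.14, with 3 of 26 higher and 5 adjusted over the list alone (adjusted p = 0.000199, but adjusted p = 0.108 with an estimated correlation). They also passed fry (adjusted p = 0.0111) and mixed fry (adjusted p = 2.28e-05), and kept their call in 22 of 23 other settings. Only the antioxidant list of these 6 had members called over all genes. Immediate early genes had a median of -0.48, with 1 of 25 lower adjusted over the list alone (adjusted p = 1.26e-05, but adjusted p = 0.253 with an estimated correlation). Meninges and fibroblast markers had a median of 0.33 (adjusted p = 0.00268, but adjusted p = 0.442 with an estimated correlation). Red blood cell genes had a median of 0.79 (adjusted p = 0.0372, but adjusted p = 0.295 with an estimated correlation). The meninges call was lost without WT_Veh 4 (median 0.203, adjusted p = 0.0531) and the red blood cell call without WT_Veh 2 or AD_Veh 2, 3 or 4 (0.0514 to 0.122). The latter was also lost with the filter of 1 FPKM, where its median was 0.486 (adjusted p = 0.0867), and its median without AD_Veh 3 was 0.501. The called antioxidant members were heme oxygenase Hmox1 (4.58 ± 1.08 against 1.65 ± 0.437 FPKM), the peroxiredoxin Prdx6 and the transcription factor Nfe2l2.

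Neuronal lists were not called between genotypes. Excitatory neuron markers had a median of 0.02 (adjusted p = 0.982), inhibitory neuron markers -0.15 (adjusted p = 0.0895) and synapse genes 0.00 (adjusted p = 0.79). The same held for oligodendrocyte precursors (0.10), endothelial and mural cells (-0.02), choroid plexus (-0.07), striatum (-0.14), hippocampus (0.05) and thalamus and hypothalamus (-0.02). Mitochondrially encoded genes (-0.19), nuclear oxidative phosphorylation (0.02), the unfolded protein response (0.04), heat shock (-0.04), amyloid precursor protein processing and clearance (0.07), circadian clock (-0.05) and glucocorticoid response genes (-0.11) were not called by camera either (adjusted p from 0.138 to 0.99), although the amyloid precursor protein list passed mixed fry (adjusted p = 0.038). Within them, the chaperone gene Clu (260 ± 15.7 against 181 ± 28.3 FPKM, adjusted p = 0.00359) and the stress-induced Atf3 (log2 0.83, adjusted p = 0.034) rose.

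The falls were smaller than the rises. The retinoid isomerase gene Rpe65 fell from 2.57 ± 0.44 to 0.876 ± 0.34 FPKM (log2 -1.18, SE 0.24, adjusted p = 0.00402). Apold1 fell from 3.06 ± 1.72 to 0.989 ± 0.163 (log2 -1.13, SE 0.26, adjusted p = 0.0128), and Trank1 from 26.6 ± 3.26 to 18.4 ± 2.75 (log2 -0.53, SE 0.12, adjusted p = 0.00773). Kirrel2, Qtrt1 and Dimt1 fell with log2 fold changes of -0.62, -0.58 and -0.57. Of 34 other settings, the call was lost in 2 for Rpe65, 5 for Apold1, 3 for Trank1, 4 for Kirrel2, 8 for Qtrt1 and 6 for Dimt1. With 1 library left out, Apold1 lost it without WT_Veh 4 or 5 (adjusted p from 0.0552 to 0.057) and Qtrt1 without WT_Veh 1 or 2 or AD_Veh 4 (0.0507 to 0.0832). The long noncoding RNA genes Mir124a-1hg (log2 -0.68) and Snhg11 (log2 -0.60) fell as well, as did Ddb2 (log2 -0.59) and Pnisr (log2 -0.50). These 4 lost their calls in 19, 18, 25 and 23 of 34 other settings. With 1 library of these 2 groups left out, the call of Mir124a-1hg was kept only without WT_Veh 3 or AD_Veh 1 (otherwise adjusted p from 0.0597 to 0.175) and that of Snhg11 only without WT_Veh 2, WT_Veh 5 or AD_Veh 5 (0.0626 to 0.153). Ddb2 kept its call only without WT_Veh 3 or AD_Veh 2 (0.0547 to 0.163) and Pnisr only without AD_Veh 5 (0.0576 to 0.153). The called Atf3 and Nfe2l2 lost theirs in 13 and 16 of 34. Among these settings were those without WT_Veh 1, 2 or 3 or AD_Veh 1, 2 or 3 for Atf3 (adjusted p from 0.0729 to 0.1). For Nfe2l2 they were those without WT_Veh 1, 2, 3 or 5 or AD_Veh 1, 3 or 4 (0.0576 to 0.154). The number of called genes was 309 in males alone, 215 in females alone and 811 with array weights. Across genes, which are not independent replicates, fold changes followed the GC content of the gene (Spearman 0.434), and 464 of the 510 calls were kept after a GC correction that called 556 genes.

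**Figure D2:**
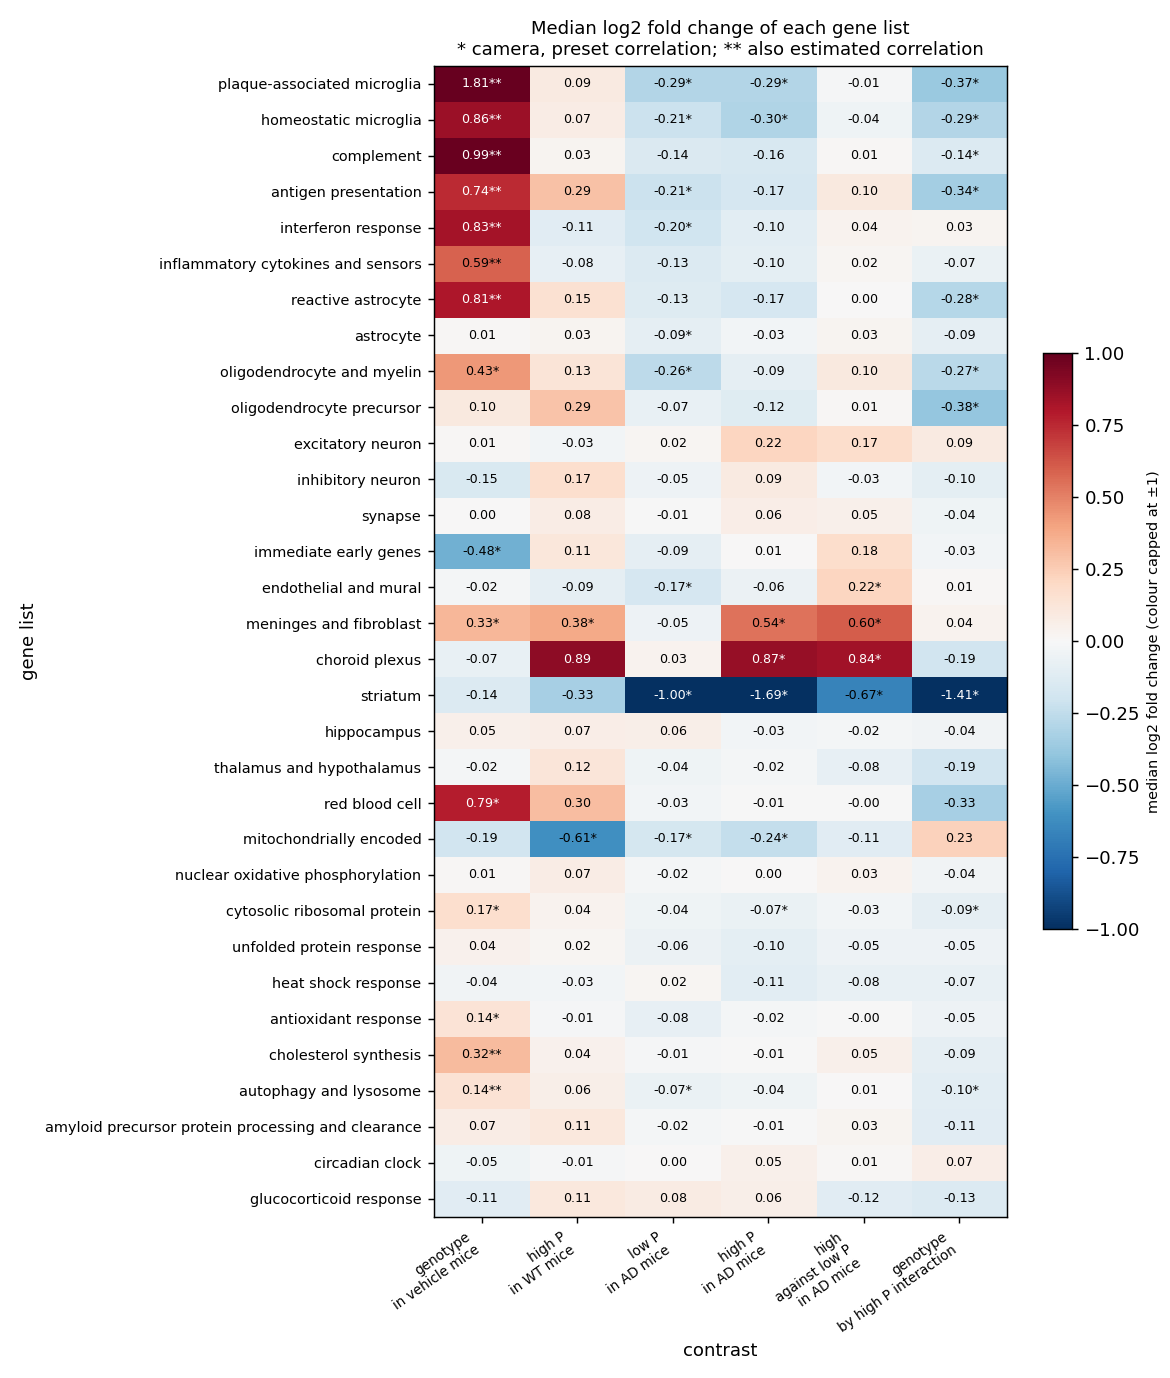
Each cell gives the median log2 fold change of a gene list (vertical axis) in a contrast (horizontal axis), coloured on a scale that stops at ±1. A single asterisk marks a call with the preset correlation and a pair of asterisks a call that also held with an estimated correlation. All calls of the stronger kind stand in the genotype column, where the plaque-associated microglia list reaches 1.81.

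High P in wild-type mice was compared with vehicle to ask what the compound changed without the transgenes. Of 13 mitochondrially encoded genes, 4 were called lower and 2 higher, and the 4 lower ones encode subunits of respiratory complex I. Of these, mt-Nd1 (ENSMUSG00000064341, mitochondrial genome 2751 to 3707 in mm10) dropped from 7080 ± 456 to 4500 ± 196 FPKM (log2 -0.65, SE 0.16, adjusted p = 0.0368). Likewise mt-Nd2 fell from 4810 ± 587 to 2930 ± 172 and mt-Nd4 from 3470 ± 280 to 2210 ± 221. These 3 lost their calls in 19, 21 and 20 of 34 other settings, and with a GC correction the log2 fold change of mt-Nd1 was -0.24 (adjusted p = 0.428, up to 1 over all settings). Its call was kept without WT_Veh 1 or WT_HighP 5 and lost without any other single library of these 2 groups (adjusted p from 0.0542 to 0.117). Reads of mitochondrially encoded genes made up 4.32% ± 0.312 of each WT_HighP library and 6.28% ± 0.324 of each WT_Veh library (n = 5 each, exact p = 0.00794). Apoe, the main lipid carrier of the brain (ENSMUSG00000002985, chromosome 7 from 19696109 to 19699188), rose from 269 ± 94.2 to 579 ± 118 FPKM (log2 1.15, SE 0.26, adjusted p = 0.0356). This call was also lost without any single library of these 2 groups other than WT_Veh 1 and WT_HighP 5 (adjusted p from 0.0505 to 0.117), and with a GC correction the log2 fold change was 0.73 (adjusted p = 0.0807, up to 0.946 over all settings). In all, 228 genes were higher and 294 lower in WT_HighP, and 213 of these 522 differed by at least 1.5-fold. No gene was called in males alone, with no filter or without the 4 libraries with high Ttr, while females alone gave more calls. The fits of 1 sex and those without the 4 libraries held fewer mice. The median GC content was 57.2% in the higher genes, 42.2% in the lower genes and 50% in all tested genes. The slope of expression on GC content was higher in WT_HighP (0.223 ± 0.0569 log2 units per 10 GC points) than in WT_Veh (-0.181 ± 0.202; exact p = 0.00794). The share of mitochondrial reads also varied with this slope among mice given the same dose. It was 6.69% and 6.83% in AD_LowP 1 and 2 (slopes -0.375 and -0.367), and 3.87% and 3.63% in AD_LowP 4 and 5 (0.197 and 0.1995). Within WT_HighP it did not, as WT_HighP 2 had the highest slope (0.286) and the highest share (4.71%). The lower share in WT_HighP was not tested apart from the GC slope. Across genes, fold changes followed GC content with a Spearman correlation of 0.843.

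Besides Apoe, rises of more than 2-fold were seen for the growth factor binding protein Igfbp2 (22.1 ± 6.87 against 9.63 ± 2.52 FPKM, log2 1.14, adjusted p = 0.0263) and the ubiquitin ligase Stub1 (31.3 ± 2.75 against 15.1 ± 4.13, log2 1.06). Grrp1, Scand1, Lzts2, Lor, Tmem160 and the mitochondrial ribosomal protein gene Mrpl54 rose with log2 fold changes between 1.05 and 1.21. The overlapping gene mt-Atp8 rose from 2.94 ± 1.21 to 10.7 ± 3.51 FPKM, a level that is uncertain because it shares sequence with mt-Atp6. Falls were seen for the splicing kinase Clk1 (7.15 ± 0.781 against 13.1 ± 2.53 FPKM, log2 -0.82, adjusted p = 0.0296) and the ATP synthase component Atp5mpl (log2 -0.85). The ribosomal protein genes Rps27 (log2 -1.59), its copy Rps27rt (log2 -2.14) and Rpl23a (log2 -1.27) also fell, and all have near-identical copies elsewhere, so their levels are uncertain. The mitochondrial tRNA genes mt-Tp (log2 -2.49), mt-Tl2, mt-Ts2 and mt-Tn and the microRNA gene Mir3058 fell too, but they are shorter than the selected fragments and their levels are also uncertain. With single libraries of these 2 groups left out, the calls of Igfbp2, Clk1 and Rpl23a were lost in 6 of 10 cases. Those of the other called genes named here were lost in 8 or 9 of 10. Of all these genes, only Rpl23a stayed called after a GC correction.

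By list, nuclear oxidative phosphorylation genes went both ways, with 5 higher and 1 lower of 47 (13 and 8 adjusted over the list alone; mixed fry adjusted p = 0.000848). This was 1 of 8 lists that passed mixed fry. Cox8a rose (317 ± 55.8 against 158 ± 51 FPKM), as did Ndufb8 (log2 0.57) and Cox5a (log2 0.34), while Ndufa5 fell (log2 -0.45). Of 47 cytosolic ribosomal protein genes, Rpl34 (log2 -0.64) and Rps21 (log2 -0.72) fell, against 5 higher and 6 lower adjusted over the list alone. The mitochondrially encoded list had 2 members higher and 4 lower of 13 (2 and 8 adjusted over the list alone), with a median of -0.61 and a mean of -0.20 (adjusted p = 0.0428, but adjusted p = 0.913 with an estimated correlation). Meninges and fibroblast markers had a median of 0.38 (adjusted p = 0.0283, but adjusted p = 0.913 with an estimated correlation), with 1 of 14 called, the prostaglandin synthase Ptgds (270 ± 68.1 against 150 ± 73.2 FPKM). Choroid plexus markers had a median of 0.89 and were not called (adjusted p = 0.155). Ttr, the main transcript of choroid plexus, stood at 671 and 820 FPKM in WT_HighP 1 and WT_HighP 2 and at most at 58.2 in the other libraries of both groups. The circadian transcription factor Dbp rose from 18.7 ± 3.29 to 34.4 ± 2.94 FPKM. Gfap (43.2 ± 9.43 against 27.1 ± 7.26 FPKM) and C1qa (33.6 ± 6.06 against 20.1 ± 6.65) were not called (adjusted p = 0.062 for both). The meninges call was lost without WT_Veh 4, WT_Veh 5 or WT_HighP 5 (adjusted p from 0.0624 to 0.104) and the mitochondrial call without WT_Veh 1, WT_Veh 4 or WT_HighP 5 (0.0651 to 0.107). Both were also lost with the filter of 1 FPKM (adjusted p = 0.0562), and the mitochondrial call with the replicate block (0.0524), the sex covariate (0.0538) and the GC correction, which moved the median to -0.109 (adjusted p = 0.991). With quantile normalization the mitochondrial median was 0 (adjusted p = 0.831), but that step sets the highest values of all libraries equal. The count of called genes was 2724 without WT_Veh 1, 64 without WT_Veh 2, 88 without WT_Veh 3, 3 without WT_HighP 4, 1 without WT_Veh 4, WT_HighP 1 or WT_HighP 2, and 0 without WT_Veh 5 or WT_HighP 3. After a GC correction, 9 of the 522 calls were left: Rpl23a, Rpl34, Rpl37a, Eno1b and Gm13680 (lower) and Ndufb6, Gm13340, Mir124a-3 and Gm22973 (higher).

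**Figure D3:**
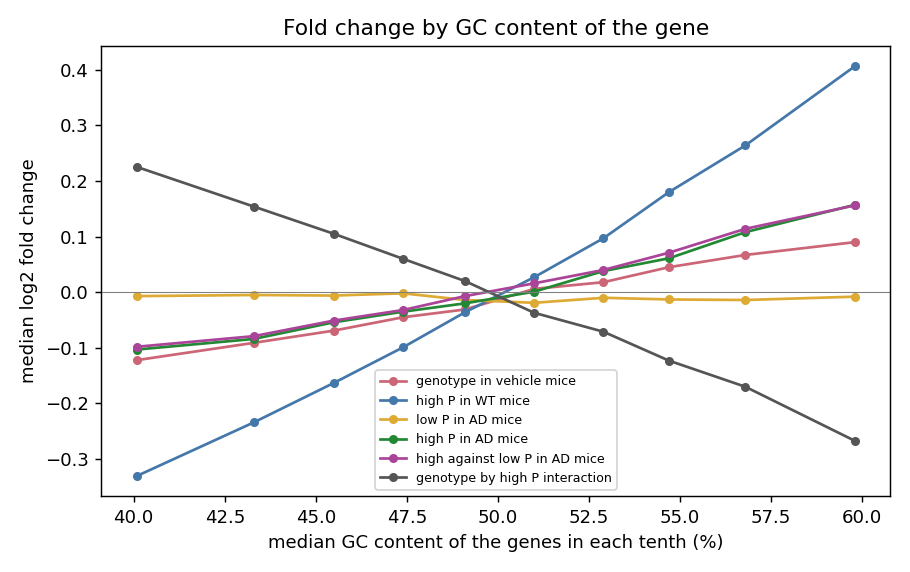
Lines give the median log2 fold change of the genes in each of 10 bins of GC content (horizontal axis, %) for the 6 contrasts. For high P in WT mice the median runs from -0.33 in the bin with the lowest GC content to 0.41 in the highest, and for low P in AD mice all medians lie between -0.019 and -0.002.

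**Figure D4:**
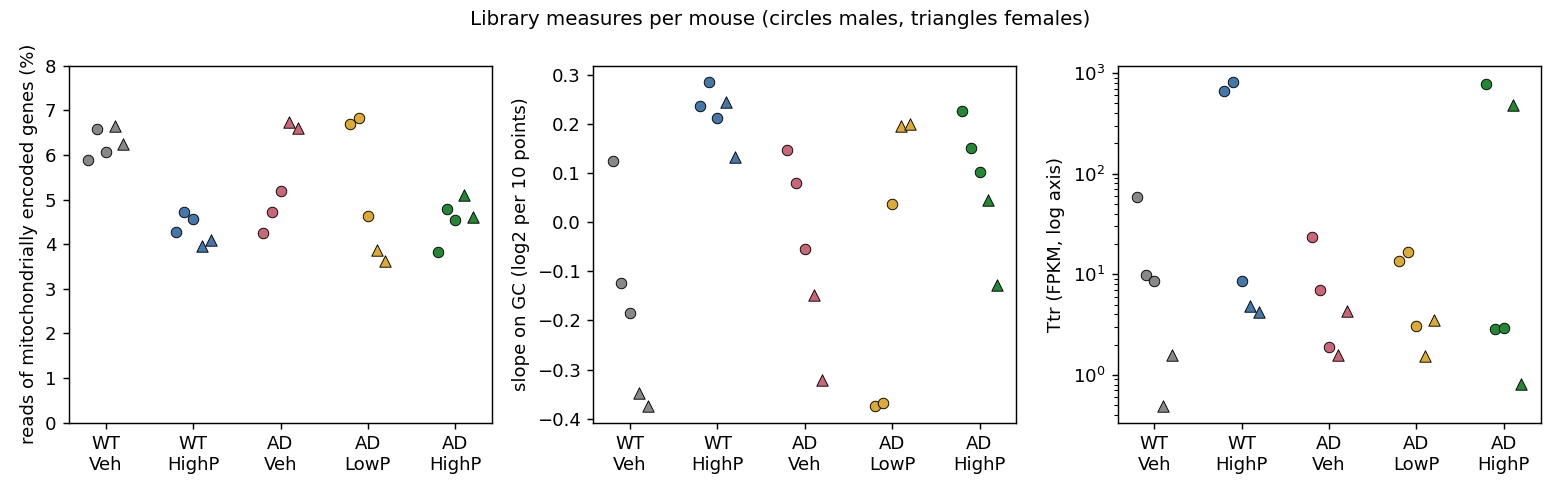
Points are single mice (circles males, triangles females) by group, with the share of reads from mitochondrially encoded genes, the slope of expression on GC content and the level of Ttr on a log axis. WT_HighP libraries lie between 3.96% and 4.71% mitochondrial reads and WT_Veh libraries between 5.89% and 6.64%, while AD_LowP libraries alone span 3.63% to 6.83%. The 4 libraries with high Ttr, all given high P, stand between 484 and 820 FPKM.

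Low P in AD mice was compared with vehicle to ask which changes of the 5xFAD cortex a low dose altered. No gene was called by limma. An unadjusted p under 0.05 was found for 491 genes, 2.98% of those tested. Of 100 splits of the same libraries, the real one included, 89 gave at least as many, so this count is within what other splits give. Limma voom on recovered reads called 0, with 523 at an unadjusted p under 0.05. The smallest adjusted p was 0.248, for Gm14303 (10.2 FPKM against 26.9 in AD_Veh, log2 -1.30). The list members named here were those with the smallest p for low P. Among them, some genes raised by genotype had lower means in AD_LowP. Cst7 stood at 39.8 ± 12.3 FPKM in AD_LowP and 56.8 ± 16.6 in AD_Veh, and Ctsd at 215 ± 20.7 and 269 ± 48.5. Cd74 stood at 17.3 and 27.8 FPKM and Ctss at 90.4 and 119, and none of the 4 was called. Other genes raised by genotype did not have lower means, such as Cebpa (13.7 FPKM in AD_LowP and 13.1 in AD_Veh). In the plaque-associated microglia list, 31 of 32 members had lower means in AD_LowP, with a median of -0.29 (adjusted p = 2.13e-13, but adjusted p = 0.235 with an estimated correlation), and 0 members passed adjusted over the list alone. The per-mouse score of this list was lower in AD_LowP with an exact p of 0.0238, which after adjustment over the 32 lists was 0.571.

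A further 9 lists passed with the preset correlation, all with lower medians in AD_LowP and 0 members called. Homeostatic microglia genes had a median of -0.21 with all 15 means lower (adjusted p = 6.06e-06, but adjusted p = 0.566 with an estimated correlation). All 19 means were lower for endothelial and mural markers at -0.17 (adjusted p = 6.06e-06, but adjusted p = 0.566 with an estimated correlation). Antigen presentation (-0.21) and interferon response genes (-0.20) each had an adjusted p of 0.00032, but an adjusted p = 0.578 with an estimated correlation. The same estimated value was found for astrocyte markers (-0.09, preset 0.0187), striatal markers (-0.997, preset 2.54e-08) and mitochondrially encoded genes (-0.17, preset 0.00809). Oligodendrocyte and myelin genes (-0.26) had an adjusted p of 0.00108, but an adjusted p = 0.711 with an estimated correlation. Autophagy and lysosome genes (-0.07) had an adjusted p of 0.00231, but an adjusted p = 0.566 with an estimated correlation. Leaving out AD_LowP 1 ended the calls of antigen presentation (adjusted p = 0.0955), interferon response (0.13) and autophagy and lysosome genes (0.0955), and leaving out AD_Veh 3 ended those of the last 2 (0.0724 and 0.0619). The antigen presentation median was then -0.124, and the interferon response median -0.13 and -0.114. The astrocyte call was lost without AD_Veh 4 (0.112) or AD_LowP 4 (0.329, median -0.048). The oligodendrocyte call was lost without AD_Veh 1 (0.0588), AD_Veh 3 (0.171) or AD_LowP 4 (0.702), and the mitochondrial call without AD_Veh 4 or 5 (0.386 and 0.146) or AD_LowP 4 or 5 (0.12 and 0.557). The oligodendrocyte median was then -0.148, -0.143 and -0.091, and the mitochondrial median -0.07, -0.109, -0.083 and -0.05. With the striatum score as a covariate the striatal median was 0.002, by construction. That covariate also ended the calls of oligodendrocyte and myelin genes (median -0.097, adjusted p = 0.561) and of mitochondrially encoded genes (median 0, adjusted p = 0.834). Drd2, a dopamine receptor of striatal neurons, stood at 17 ± 16.3 FPKM in AD_LowP and 30.3 ± 11.1 in AD_Veh. In simulated libraries with values pooled over all groups, 26% of genes changed by 1.5-fold and 70% of genes changed by 2-fold were called. These shares depended on the genes drawn and are not particular to AD_LowP and AD_Veh.

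High P in AD mice was compared with vehicle in the same way. The only gene called was Mir124a-3 (ENSMUSG00000065454, chromosome 2 from 180894040 to 180894107), a microRNA gene shorter than the selected fragments, whose level is therefore uncertain. It had 20 reads over the 5 AD_HighP libraries (2 to 6 per library) and 0 over the 5 AD_Veh libraries, at least 6.61-fold higher against a floor of 3 reads over the group, for counting error only (adjusted p = 0.0198). With limma voom no gene was called, and leaving out AD_HighP 1, 2, 3 or 4 or AD_Veh 1, 3, 4 or 5 gave 0 calls each and leaving out AD_Veh 2 gave 2. The unadjusted p was under 0.05 for 983 genes (5.98% of those tested), and by voom for 967. Cst7 stood at 45.6 ± 14.3 FPKM in AD_HighP, and Mpeg1, a pore-forming protein of phagocytes, at 26.3 against 37 in AD_Veh. The lysosomal protein Cd68 stood at 26.4 against 35.9 FPKM and Itgb2 at 5.78 against 8.11, and none of the 4 was called.

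Striatal markers had a median of -1.69 in AD_HighP, with 15 of 16 lower adjusted over the list alone and 0 over all genes (adjusted p = 7.3e-15, but adjusted p = 0.489 with an estimated correlation; exact p of the score 0.0238). The opioid precursor Penk stood at 44.5 ± 43.5 FPKM against 150 ± 67.4, and Drd2 at 8.93 ± 11.3 against 30.3 ± 11.1. The plaque-associated microglia list had a median of -0.29 with 31 of 32 means lower (adjusted p = 3.32e-11, but adjusted p = 0.448 with an estimated correlation; exact p of the score 0.0635). The homeostatic microglia list had a median of -0.30 with 13 of 15 lower (adjusted p = 1.05e-05, but adjusted p = 0.489 with an estimated correlation; exact p of the score 0.0397). Meninges and fibroblast markers had a median of 0.54 with 2 of 14 higher adjusted over the list alone (adjusted p = 8.65e-07, but adjusted p = 0.489 with an estimated correlation; exact p of the score 0.0159). Ptgds stood at 367 ± 161 against 203 ± 43 FPKM. Choroid plexus markers had a median of 0.87 (adjusted p = 0.00747, but adjusted p = 0.629 with an estimated correlation), and -0.27 without the 4 libraries with high Ttr. Of these, AD_HighP 1 and AD_HighP 4 stood at 788 and 484 FPKM of Ttr, and the call was lost without either (medians 0.404 and 0.502, adjusted p = 0.223 and 0.123). Mitochondrially encoded genes (-0.24, adjusted p = 0.00417, but adjusted p = 0.564 with an estimated correlation) also passed with the preset correlation. With the striatum score as a covariate their median was -0.008 and the call was lost (adjusted p = 0.958), as it was with quantile normalization (adjusted p = 0.289). So did cytosolic ribosomal proteins (-0.07, adjusted p = 0.000295, but adjusted p = 0.714 with an estimated correlation), although not without AD_HighP 5 (median -0.027, adjusted p = 0.126). Among the remaining lists, 2 complement genes were lower adjusted over the list alone, and that list was not called (adjusted p = 0.058). After adjustment over lists, no score passed (smallest adjusted p = 0.381). In simulated libraries with values pooled over all groups, 40% of genes changed by 1.5-fold and 71% of genes changed by 2-fold were called. These shares depended on the genes drawn and are not particular to AD_HighP and AD_Veh.

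**Figure D5:**
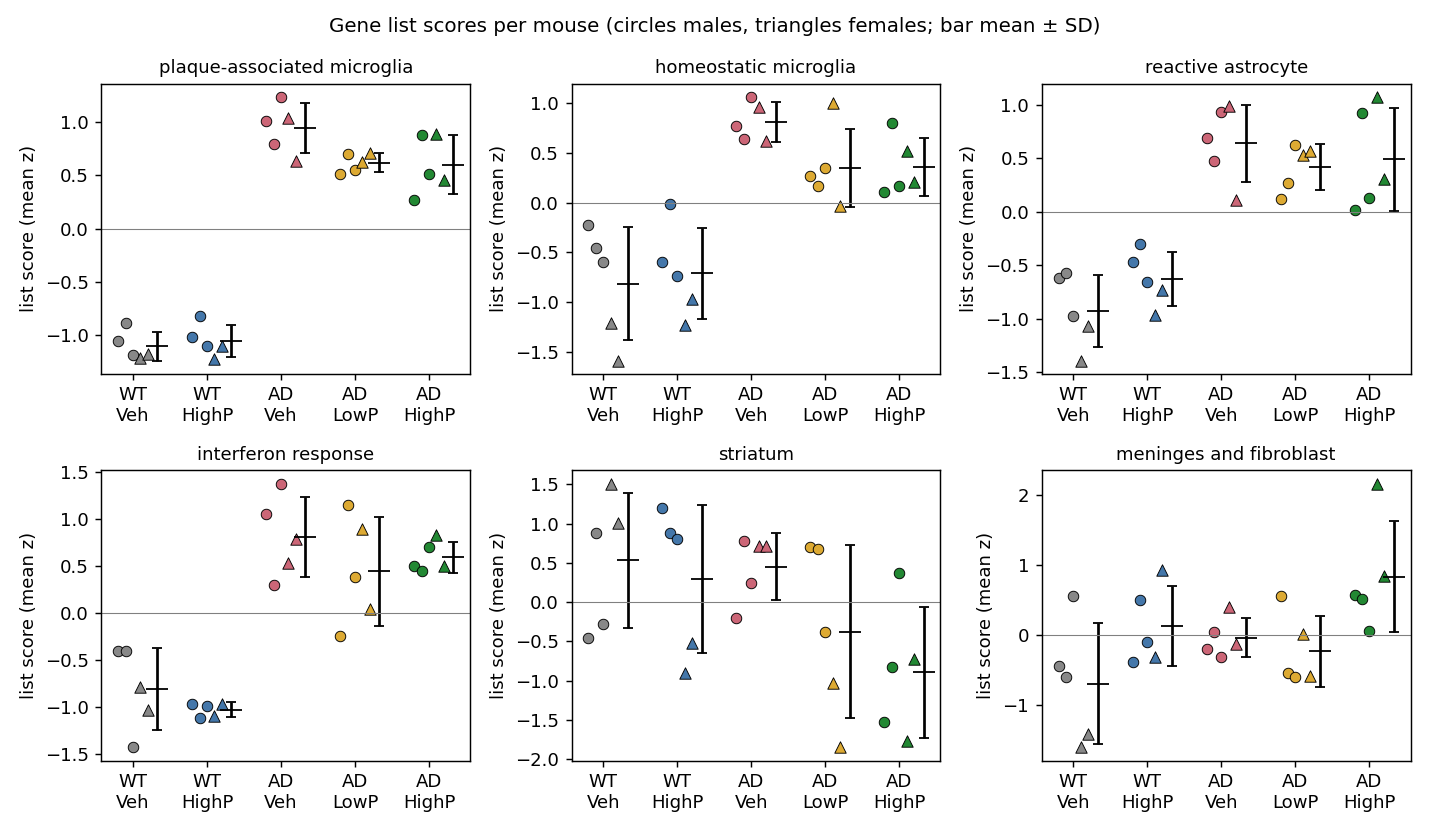
Points are single mice (circles males, triangles females), bars the group mean ± SD, and the vertical axis the mean standardised log2 level over the members of each of 6 lists. The plaque-associated microglia scores of all 15 AD mice lie above those of all 10 WT mice, and the 3 AD groups overlap.

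The high dose was compared with the low dose in AD mice. By limma 0 genes were called (1019, or 6.19% of those tested, at an unadjusted p under 0.05) and by voom 0 (1072). The smallest adjusted p was 0.144 for Gm8822 (log2 -0.58, limma). The plaque-associated microglia list had a median of -0.01 between the doses (adjusted p = 0.733). Meninges and fibroblast markers had a median of 0.60, with 9 of 14 higher adjusted over the list alone (adjusted p = 2.78e-08, but adjusted p = 0.862 with an estimated correlation). The collagen gene Col1a1 stood at 1.56 FPKM with the high dose and 0.738 with the low dose. Endothelial and mural (0.22, adjusted p = 0.00686), choroid plexus (0.84, adjusted p = 0.00843) and striatal markers (-0.67, adjusted p = 0.00505) passed with the preset correlation, but each had an adjusted p = 0.973 with an estimated correlation. The endothelial call was lost without AD_LowP 4 or 5 or AD_HighP 2 or 4 (adjusted p from 0.0653 to 0.281). The choroid plexus call was lost without AD_LowP 4 or 5 or AD_HighP 1 or 4 (0.0682 to 0.219), and the striatum call without AD_LowP 1 or 2 or AD_HighP 1 or 4 (0.0642 to 0.193). The endothelial median was 0.068 without AD_LowP 4, 0.14 without AD_HighP 2 and 0.152 without AD_HighP 4, and the choroid plexus median was 0.372 without AD_HighP 1 and 0.46 without AD_HighP 4. The striatal median was -0.32 and -0.301 without AD_LowP 1 and 2 and -0.405 and -0.362 without AD_HighP 1 and 4. Without the 4 libraries with high Ttr, of which 2 are in these groups, it was -0.044 (adjusted p = 0.833) and the choroid plexus median -0.3 (adjusted p = 0.327).

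The interaction asked whether the change with high P differed between genotypes. By limma 0 genes were called (1138, or 6.92% of those tested, at an unadjusted p under 0.05) and by voom 0 (1142). The smallest adjusted p by limma was 0.546. The genes with the smallest p were Gm13680 (log2 1.28), the myeloid transcription factor Cebpa (log2 -0.95), Gm43089 (log2 -2.61), Gm6505 (log2 -1.89) and 6720427I07Rik (log2 1.17). The SE of this contrast was larger (median 0.213) than that of the pairwise ones (0.15). In simulated libraries 16% of genes with a 1.5-fold and 49% with a 2-fold interaction were called. For the change with high P, 10 lists had a lower median in AD than in WT mice with the preset correlation. The plaque-associated microglia (-0.37, adjusted p = 3.42e-06), homeostatic microglia (-0.29, adjusted p = 0.001), antigen presentation (-0.34, adjusted p = 0.000637) and reactive astrocyte lists (-0.28, adjusted p = 0.000664) each had an adjusted p = 0.534 with an estimated correlation. The same estimated value was obtained for the oligodendrocyte precursor (-0.38, adjusted p = 0.00096), striatum (-1.41, adjusted p = 1.91e-05), complement (-0.14, adjusted p = 0.00848) and autophagy and lysosome lists (-0.10, adjusted p = 0.00546). The oligodendrocyte and myelin (-0.27, adjusted p = 0.00492) and cytosolic ribosomal protein lists (-0.09, adjusted p = 0.0186) had adjusted p = 0.689 and adjusted p = 0.741 with an estimated correlation. The former was lost without WT_Veh 3 (median -0.138, adjusted p = 0.171) or AD_Veh 3 (median -0.173, adjusted p = 0.0892), and the latter without WT_Veh 4 or 5, WT_HighP 1 or 2, AD_Veh 3 or 4, or AD_HighP 1 or 5 (0.0737 to 0.321). The ribosomal median lay between -0.078 and -0.027 without these libraries. It was -0.018 with the GC correction (adjusted p = 0.208) and -0.025 with quantile normalization (adjusted p = 0.472), and that normalization also ended the autophagy and lysosome call (median -0.066, adjusted p = 0.066). With the striatum score as a covariate the medians of striatum (-0.028, adjusted p = 0.918, by construction) and oligodendrocyte and myelin genes (-0.032, adjusted p = 0.517) were near 0. Those of complement (-0.185) and cytosolic ribosomal protein genes (-0.107) were no smaller than before, although their calls were lost (adjusted p = 0.0956 each). Without the 4 libraries with high Ttr, 3 of the 10 lists were called. The medians of the lists not called were then -0.161 for striatum (adjusted p = 0.743), -0.051 for oligodendrocyte and myelin (0.59), -0.045 for cytosolic ribosomal protein (0.662) and -0.176 for homeostatic microglia genes (0.197). They were -0.241 for oligodendrocyte precursor (0.0613), -0.131 for complement (0.197) and -0.103 for autophagy and lysosome genes (0.0613). Fold changes of this contrast also followed GC content (Spearman -0.677 across genes).

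Genes called between genotypes were followed into the P groups to ask whether their changes were smaller under P. To keep the AD_Veh libraries of both contrasts apart, 3 of them defined the genotype genes and the remaining 2 served as control for P, in 10 splits. Of the genotype genes, 72.2% ± 14.1 (SD over splits) changed in the opposite direction with low P and 75.4% ± 15.3 with high P. In 100 simulations in which P changed nothing the share was 49.6% (central range 21.5% to 80.9%). With 2 AD_Veh libraries defining the genes and 3 as control, the shares were 77.2% and 82.7%. With the 100 genes of smallest p they were 81.9% and 87.5%. No simulations were run for these settings. The slope of the P change on the genotype change was -0.109 with low P and -0.129 with high P, against a simulated range of -0.149 to 0.143. For this share and slope, each simulation used a single random split, while the observed values are means over 10 splits. A mean over splits varies less than a single split. The simulated ranges of this share and slope therefore cannot decide whether the changes were smaller under P. With all 5 AD_Veh libraries in both contrasts, the opposite share was 84.9% with low P and 86.9% with high P, against a simulated 65.1% (36.9% to 89.4%). In 7 and 5 of 100 simulations the share was as high. The fold changes of low and high P had a correlation of 0.482 and a covariance of 0.0265 across genes, against a simulated 0.485 and 0.026 from the shared controls alone. With separate controls the correlation was 0.032.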

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

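The tests of the plaque-associated microglia list with GC bins, with a GC correction and with the striatum score as covariate were chosen only after the result was seen.

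The many genes called for high P in wild-type mice were weighed first. Choroid plexus tissue in WT_HighP 1 and 2 is argued against as the main source, since without these libraries the median change of the called genes was 0.912 of its size with them. A GC-dependent difference between libraries remains a candidate explanation. The relation of each gene to the GC slope within the AD groups gave the right sign for 96.2% of the 522 called genes (76.9% of all genes). The predicted median change was 0.297 against an observed 0.531. For the 521 called genes with a known GC content, the GC correction lowered that median to 0.245 and the median SE from 0.131 to 0.099. After it 9 calls were left because the changes shrank more than their error, with 515 of the 521 keeping their sign. Chance is argued against as the only source of the count, since 1 of 100 splits, the real one, gave as many genes (522 against at most 6 in the others). That is the lowest number such splits can give, and it was not adjusted over the 6 contrasts, so chance is not excluded. An effect of P on these genes stays open. It was not tested apart from the GC-dependent difference, because every WT_HighP library had a higher GC slope than every WT_Veh library.

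The lower plaque-associated microglia list under P in AD mice was weighed next. A GC-dependent difference is argued against for low P, since its fold changes did not follow GC content and the GC bin median farthest from 0 was -0.019, against -0.292 for the list. For high P, whose fold changes did follow it (Spearman 0.536), it is argued against since with the GC correction the list median stayed at -0.301 and kept its call. A smaller share of striatal tissue is argued against as well, since with the striatum score as covariate the medians were -0.317 and -0.264. Of 100 splits of the libraries, 2 gave a median as far from 0 as low P (-0.292, highest other 0.295) and 7 as far as high P (-0.292, highest other 0.366). Fewer than 5 splits had been set down as a sign against chance, but that bound was wrong for a list picked out of 32 because it was low. Adjusted over the 32 lists, the exact permutation p of its score was 0.571 for low P and 0.457 for high P, so chance is excluded for neither dose. Both comparisons share the AD_Veh libraries, and with an estimated correlation the adjusted p was 0.235 and 0.448. The doses differed by a median of -0.012 (adjusted p = 0.733). An effect of P on microglia stays open for both doses.

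The lower striatal markers in AD_HighP were weighed last. Less striatal tissue in the dissection predicts that other genes which follow the striatum score within the WT groups are lower too, and 97% of 100 such genes outside the list were lower in AD_HighP, against 49.4% of all genes. Their median log2 fold change was -0.595, against a predicted -0.781. This is consistent with a difference in the tissue taken, and Drd2 ranged from 0.611 to 28.1 FPKM within AD_HighP. An effect of high P on striatal genes stays open, as it was not tested apart from the tissue.

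Other splits of the same libraries were drawn for each count, 100 per contrast with the real one included. For genotype, 2 splits gave at least the 510 called genes. The other one gave 943 and put WT_Veh 1 and 2 with AD_Veh 1, 2 and 3, all males with a mean GC slope of 0.035 against -0.275 in the rest, which points to a structure of the samples besides genotype. Chance is not excluded by these splits for the count of 510 genes, since another split gave more and the result was not adjusted over the contrasts. Nor is chance excluded for the number of called lists (15, reached by 21 splits, highest other 18). For the lists of high P in WT mice it is not excluded either (2, reached by 97 splits, highest other 19). By unadjusted p under 0.05, 89 splits gave at least the 491 genes of low P (highest other 5594), 14 the 983 of high P in AD mice (2402), 37 the 1019 of high against low P (3856) and 18 the 1138 of the interaction (4527), so chance is excluded for none of these. The highest split of each of the first 3 parted libraries both by GC slope and by striatum score. The mean GC slopes were 0.132 and -0.253 for low P, 0.135 and -0.114 for high P and -0.147 and 0.164 for high against low P. The mean striatum scores were -0.537 and 0.61, -0.792 and 0.346, and 0.128 and -1.4. The called lists of low P (10, reached by 20 splits, highest other 18), high P (7, by 61, highest other 18), high against low P (4, by 93, highest other 18) and the interaction (10, by 31, highest other 19) leave chance open as well.

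Single libraries stood apart from the other 4 of their group in 10 of 205 checks of library measures and list scores, where chance alone gives about 10.25. Ttr was 58.2 FPKM in WT_Veh 1 (others 0.485 to 9.75) and 23.7 in AD_Veh 1 (others 1.57 to 7.03). The oligodendrocyte and myelin score was -1.36 in WT_HighP 5 (others 0.21 to 0.449), the oligodendrocyte precursor score 1.44 in WT_HighP 2, and the autophagy and lysosome score -0.456 in WT_HighP 2. The excitatory neuron score was -1.29 in AD_Veh 5, and the glucocorticoid response score 1.69 in AD_LowP 5. In AD_HighP, the hippocampus score was 1.14 and the cholesterol synthesis score -0.211 in library 4, and the heat shock score 0.373 in library 5.

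The change with high P differed between AD and WT mice, by the interaction term and with the preset correlation only, for 10 lists, all with a negative median. The medians were -0.368 for plaque-associated microglia, -0.294 for homeostatic microglia, -0.138 for complement, -0.339 for antigen presentation, -0.283 for reactive astrocyte, -0.267 for oligodendrocyte and myelin, -0.384 for oligodendrocyte precursor, -1.407 for striatum, -0.091 for cytosolic ribosomal protein and -0.102 for autophagy and lysosome genes. With an estimated correlation the smallest adjusted p of these lists was 0.534. Without the 4 libraries with high Ttr, 3 of them were called, and the medians of the striatum and of the oligodendrocyte and myelin list were -0.161 and -0.051.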

How the results depend on the processing

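The settings with a GC correction, a GC slope or striatum covariate, without 4 libraries with high Ttr, or with 1 sex were chosen only after the results were seen. The genotype count stayed between 381 and 570 when any library of WT_Veh or AD_Veh was left out, and its lists between 14 and 16. It moved beyond 1.5 times with array weights (811, with 79% instead of 91.2% higher), in males (309), in females (215) and in females after GC correction (238), the last 3 with fewer mice. With the estimated correlation 9 of its 15 lists were called.

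The 522 genes of high P in WT mice became 0 with no filter, 806 with a mean of at least 1 FPKM, 840 with the sex covariate, 9 with the GC correction, and 0 with the GC slope covariate. It became 959 with the striatum covariate, 19 with GC correction and that covariate, and 0 without the 4 libraries with high Ttr. It was 1513 with only the groups compared, 321 without a trend, 3371 with array weights and 213 with a fold minimum. In males it was 0 and after GC correction 2, and in females it was 2278 and 240. The female fits compared 2 with 2 mice, with GC slopes of 0.245 and 0.133 in WT_HighP and -0.348 and -0.375 in WT_Veh. The female count therefore cannot be read as a response of females to P. Left-out libraries gave 0 to 2724: 2724 without WT_Veh 1, 64 without WT_Veh 2 and 88 without WT_Veh 3. The count was 1 without WT_Veh 4, WT_HighP 1 or WT_HighP 2, 3 without WT_HighP 4 and 0 without WT_Veh 5 or WT_HighP 3. Its 2 lists became 0 with a mean of at least 1 FPKM, 1 with quantile normalization, 1 with the sex covariate, 6 with the GC correction, 5 without the 4 libraries, 0 with the estimated correlation or fry and 8 with mixed fry. Left-out libraries gave 0 to 6 (6 without WT_Veh 2 or WT_HighP 4, 5 without WT_HighP 3, 1 without WT_Veh 5 or WT_HighP 5, 0 without WT_Veh 4).

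For low P, 2 genes were called with no filter, 2 in males, 1 in males after GC correction, and 0 with any library of its groups left out. In females 751 were called, and 86 after GC correction. These female fits compared 2 with 2 mice. The GC slopes were 0.197 and 0.1995 in AD_LowP females and -0.148 and -0.322 in AD_Veh females. The female counts therefore cannot be read as a response of females to P. The 10 lists of low P became 0 with the estimated correlation, fry or mixed fry, and 7 to 14 with a library left out. For high P in AD mice, 0 genes were called with no filter, the striatum covariate alone or with GC correction, the count test, without the 4 libraries, or in males with or without GC correction. In females 14 were called, and 7 after GC correction. Left-out libraries gave 0 to 2 genes: 2 without AD_Veh 2, and 0 without AD_Veh 1, 3, 4 or 5 or AD_HighP 1, 2, 3 or 4. Its 7 lists became 12 with GC correction, 13 without the 4 libraries and 0 with the estimated correlation, fry or mixed fry. Left-out libraries gave 6 to 15 (15 without AD_Veh 4, 13 without AD_Veh 5 or AD_HighP 2 or 4, 11 without AD_Veh 2). For high against low P, 329 genes were called in males, 4 in males and 1 in females after GC correction, and 1 without a trend. The GC slopes were 0.226, 0.152 and 0.101 in AD_HighP males and -0.375, -0.367 and 0.036 in AD_LowP males. The male count therefore cannot be read as a response of males to the dose. Left-out libraries gave 0 to 2 (2 without AD_LowP 5). Its 4 lists became 0 with the estimated correlation, fry or mixed fry, and 2 to 7 with a library left out (7 without AD_LowP 3, 2 without AD_LowP 4 or 5 or AD_HighP 1 or 4). For the interaction, 9 genes were called with array weights and 0 to 1 with a library left out (1 without WT_Veh 1). Its 10 lists became 3 without the 4 libraries, 0 with the estimated correlation, fry or mixed fry, and 8 to 11 with a library left out.

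The striatum list turned to 0.002 for low P and 0.006 for high against low P with the striatum covariate, which removes that score by construction. The choroid plexus list turned to -0.266 for high P in AD mice and -0.3 for high against low P without the 4 libraries that held most of its signal. Replicate numbers followed sex in every group (1 to 3 males, 4 and 5 females). At most 2 of 5 same-numbered pairs of any pairwise contrast correlated above 0.1. For AD_HighP with AD_Veh, however, 3 of 5 libraries correlated best with their own number (mean 0.107, against -0.026 for other pairs). In the other pairwise contrasts 0 or 1 did. For AD_HighP with WT_Veh, used in the interaction, 3 of 5 pairs exceeded 0.1. A pairing by number is therefore not excluded. With the replicate block, 218 genes and 1 list were called for high P in WT mice, and with GC correction as well 7; for high P in AD mice the latter gave 0 genes, and no other count moved beyond 1.5 times. The return slopes ranged from -0.126 to -0.082 for low P and from -0.161 to -0.1 for high P with a P library left out, and the opposite shares from 64.8% to 74.4% and from 72.9% to 79.4%. Median-of-ratios scaling moved nothing, and other scalings moved the median of all genes by at most 0.025. For other changes the cause was not tested.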

Other observations

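No test in this part was chosen only after its result was seen, but the genes of the first paragraph and Mir124a-3 in other groups were picked after their values were seen.

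Of the 510 genes called between genotypes, 395 belonged to no list, 350 higher and 45 lower in AD_Veh. Receptors of myeloid cells were among them. Fcgr3, a low-affinity receptor for immunoglobulin G, rose from 4.69 ± 0.404 FPKM in WT_Veh to 16.5 ± 3.02 in AD_Veh (log2 1.70, SE 0.11, adjusted p = 9.68e-11, n = 5 each, limma). It stood at 13.5 in AD_LowP and 11.2 in AD_HighP. Csf3r, the receptor of granulocyte colony-stimulating factor, rose from 1.8 to 6.4 FPKM, Tgfbr2, a receptor of transforming growth factor beta, from 3.75 to 8.28. The checkpoint receptor Lag3 rose from 3.8 to 15.8. Ly86, a partner of an innate immune receptor, rose from 1.86 to 7.9 FPKM, the NADPH oxidase subunit Cyba from 3.02 to 13.1, and the cytoskeletal adaptor Plek from 4.62 to 14.9. The myeloid transcription factor Cebpa rose from 4.52 to 13.1 and the lysosomal mannosidase Man2b1 from 6.26 to 13.7. The urea transporter Slc14a1 rose from 2.13 to 7.61 FPKM and Mamdc2 from 0.251 to 4.19.

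It was asked whether AD mice with more Thy1 RNA, a possible sign of stronger transgene expression, had higher plaque-associated microglia scores. Thy1 also differed between groups without the transgenes, at 185 ± 7.49 FPKM in WT_HighP and 155 ± 15.6 in WT_Veh (exact permutation p = 0.00794). These groups also differed in GC slope (0.223 against -0.181), so the spread of Thy1 among AD mice need not reflect the transgenes. Over the 15 AD mice Pearson's r was 0.164 (permutation p = 0.558, 100000 resamples, adjusted p = 0.954 over 3 relations) and Spearman's rho 0.086 (permutation p = 0.762). Pearson's r was 0.191 without the 2 mice farthest from the median of Thy1 and 0.277 within groups. Females and males, 6 and 9 by marker genes, differed by 0.008 in the score (females minus males; exact p = 0.954 over 1000 regroupings within groups). In log2 Thy1 they differed by 0.049 (exact p = 0.736, adjusted p = 0.954). Before the test, a p of this size was set down as a sign against each relation. However, 15 mice leave moderate relations undetected, so none of the 3 is excluded.

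Reads of Mir124a-3 were seen in both high P groups, with 21 over the 5 WT_HighP libraries (1 to 7 each) and 20 over the 5 AD_HighP libraries. There was 1 over the 5 WT_Veh libraries, there were 0 in AD_Veh and 4 over the 5 AD_LowP libraries, of which 2 held any. The gene is shorter than the selected fragments, and the numbers carry counting error only.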
